A study of Mus musculus with 6 samples.

How the data were processed

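Expression was measured in mouse pro-B cells that lack Pax5, the transcription factor that commits pro-B cells to the B lineage. Per the labels, the cells grew on ST2 cells, a bone marrow stromal line, with 5 ng/ml IL-7. They were infected with a retrovirus that carried EBF or with a control retrovirus, and GFP-positive cells were sorted 2 days later. Biotin-labelled cRNA was made from 6 microg total RNA and hybridised to Affymetrix arrays, with 3 arrays per group. The labels number the replicates within each group but do not say that they were separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The design text names a rat array. The organism label is mouse and the control probe sets carry mouse gene names, so the probe sets were read as those of a mouse array.

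The deposited values are intensities per probe set on a linear scale, from 1 upward, with 1 column per array. The software, background step and normalization that the authors used to make these intensities are not given in the sources used here. The median intensity of an array lay between 424 and 451, and the highest 2% trimmed mean was 1.03 times the lowest. The rule set in advance asked for scaling only where trimmed means differed by more than 5%, so no further scaling was applied, although the highest median was 1.06 times the lowest. No detection calls were used here. The 27 control probe sets for Bacillus transcripts had medians of 97.6 to 108 per array and reached 410 at most, and low intensities were read against these levels. The number of arrays limits the precision.

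Values were analysed as log2(intensity + 32), so fold changes are on that scale and understate the change of dim genes. Of 45101 probe sets, 64 Affymetrix controls were left out and 45037 were tested. Probe sets were named from the platform's gene table: 34945 had 1 gene symbol, 932 had several and 9160 had no listed gene. The gene IDs of 34741 of the 1-symbol probe sets were found in the RefSeq gene table of the mouse, and 0 symbols needed updating. Each of the 18193 genes was represented by its brightest probe set over all 6 arrays, chosen without regard to group. No genomic coordinates are given, because the sources used here name no genome build for the array.

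The comparison, EBF minus control, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05, and the errors given with log2 differences are limma's standard errors. Intensities are given as mean ± SD of the 3 arrays of a group. Before the data were examined, the tests, the alternatives, the rule for naming genes and 19 gene lists with 513 entries from textbook knowledge were fixed. They covered pre-BCR and BCR components, B lineage transcription factors, V(D)J recombination, genes described as repressed by Pax5, and markers of myeloid, T, NK and stem or progenitor cells. The others were the Notch pathway, Id proteins with E protein inhibitors (the Id list), the IL-7 receptor pathway, antigen presentation, adhesion and homing, and cell cycle. They also included p53 targets, the interferon response, stress genes, ST2 stromal genes and ribosomal proteins. Of the entries, 463 were measured, 48 were not matched to a gene measured here and 2 repeated another entry under a different name. Lists were tested with limma's camera, with a preset correlation of 0.01 between genes and with an estimated correlation. They were also tested with limma's fry, directional and mixed, with adjustment over the 19 lists. Fry's p-values are directional unless called mixed. Fisher's exact test of the share of changed genes in each list, one-sided for an excess, was added after the data had been seen. It takes genes as independent of each other, so its p-values do not measure the spread between arrays.

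The named genes followed a rule also fixed in advance. It named 23 genes whatever their result, of which 2 had no probe set named here. It added the 12 largest increases and 12 largest decreases among changed genes whose groups did not overlap, leaving out clone-type symbols. From each list it took the 2 largest increases and 2 largest decreases among changed members, or the 2 members with the smallest p where none passed. Every other gene named was chosen after its values were seen.

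The replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means across probe sets of above-median brightness. The correlations were 0.316, 0.251 and 0.505 for numbers 1, 2 and 3, all above the limit of 0.1, and every array correlated best with the array of its own number. The numbers were therefore taken to pair the arrays. This pairing is read from the data, since the labels give numbers alone. With 3 arrays per group there are few ways to match them, so such a match can also arise by chance. The blocked values rest on this pairing. The planned fit without the number as a block was kept as the main one. The blocked value is printed beside a result where it changed the call or moved a count by more than 1.5 times.

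The steps were tested on simulated data made from the 6 arrays' own means and spreads, with 200 of 45037 probe sets changed between EBF and control. The fit recovered 43.3% of the probe sets changed by a log2 of 0.5, 91.0% of those changed by 1 and 97.0% of those changed by 2, and 4.35% of its calls were false. The simulated noise was independent between probe sets and between arrays, without the shifts that the real arrays share. These rates therefore check the steps and need not hold for the real calls. The alternatives tried were quantile normalization, median centring, a filter on dim probe sets, a trended and robust variance model, array weights, the replicate block, pseudocounts of 8 and 128, and the mean of a gene's probe sets. A threshold of 0.01, leaving out probe sets that can cross-hybridise and leaving out each array in turn were also planned. Leaving out EBF 3 with control 2, leaving out both arrays of a number, a random block and a stromal covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.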

Results

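Gene expression was compared between 3 arrays of Pax5-deficient pro-B cells given an EBF retrovirus and 3 arrays of the same kind of cells given a control retrovirus, to show which genes respond to EBF when Pax5 is missing. EBF is a transcription factor needed for early B cell development. The arrays are called EBF 1 to 3 and control 1 to 3, after their labels. Their median intensities were 445, 439 and 444 in the EBF group and 424, 451 and 426 in the control group.

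The brightest Ebf1 probe set read 4537 ± 394 (SD, n = 3) in the EBF arrays and 4169 ± 127 (SD, n = 3) in the controls, a log2 difference of 0.12 ± 0.08 (SE; limma adjusted p = 0.469). None of the other 4 Ebf1 probe sets was higher past the threshold, and 1 of them was lower only with the replicate number as a block in the fit (log2 -0.33; adjusted p = 0.106, blocked 0.0443). Whether these probe sets lie in the part that the virus carries is not known here, so they check the labels neither way. The brightest Pax5 probe set read 933 ± 22.9 and 980 ± 40.6 (SD, n = 3 each; log2 -0.07 ± 0.07, adjusted p = 0.619), and whether it lies in the deleted part of the gene is not known here either.

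Among the largest changes were those of Gzma and Klrd1, genes of natural killer (NK) and cytotoxic cells, in opposite directions. Gzma, which encodes the granule protease granzyme A, rose 6.85-fold, from 170.5 ± 21.2 to 1402 ± 448 (SD, n = 3 per group; log2 2.78 ± 0.21, adjusted p = 0.00164). Klrd1, which encodes the NK receptor chain CD94, fell 4.17-fold, from 2646 ± 477 to 607 ± 80.8 (log2 -2.06 ± 0.15, adjusted p = 0.00118). Nkg7, a granule protein of NK and cytotoxic T cells, fell by 1.70 on the log2 scale, and Klrb1f, another NK receptor gene, fell by 1.28. Tnnt2, the cardiac troponin T gene, rose from 73.5 ± 8.82, below the median of the Bacillus control probe sets, to 674.8 ± 112 (log2 2.74 ± 0.12, adjusted p = 1.21e-04). At such a control level the size depends on the pseudocount: its log2 difference was 3.06 with the lower and 1.99 with the higher one. Another Tnnt2 probe set rose from 29.9 to 705, also from below that median, and the remaining one had a log2 difference of 0.13.

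The other large increases were in genes of varied function. They were Scn4b, a sodium channel subunit (log2 1.85 ± 0.12), Gfra2, a co-receptor for the GDNF family (1.50 ± 0.15), and Mmp13, a collagenase (1.48 ± 0.14). Akap12, a protein kinase A scaffold, rose by 1.38, Acp6 by 1.25, Col26a1 by 1.24, the chaperone gene Clgn by 1.23 and Capsl by 1.18. Ms4a1, which encodes the B cell surface protein CD20, rose 2.17-fold, from 256.1 ± 13.9 to 592 ± 41.5 (SD, n = 3 per group; log2 1.11 ± 0.08, adjusted p = 0.00118). Rsph9, a radial spoke protein of cilia, rose by 1.09. The other large decreases included Fcgr3, an IgG receptor of myeloid and NK cells (log2 -1.33 ± 0.22, adjusted p = 0.0375), Ncf1, a subunit of the phagocyte oxidase (-1.03 ± 0.07), and Il18r1, the interleukin-18 receptor (-0.99 ± 0.07). Ctla2a fell by 1.35, Crisp3 by 1.19 and the ADP receptor gene P2ry12 by 1.14. Bpifc fell from 147.7 to 57.0, below the median of the Bacillus controls, so that its size depends on the pseudocount (log2 -1.29 with the lower one, where the call was lost with an adjusted p of 0.0606, and -0.58 with the higher one). Gsn, which encodes the actin-severing protein gelsolin, fell from 1742 to 860 and Tsc22d1 from 5310 to 2600. By the rule that named them, all of these genes had EBF and control arrays that did not overlap, as did all 198 changed genes. Clgn, P2ry12 and Bpifc lost the call without any 1 array other than EBF 3 (highest adjusted p 0.169, 0.179 and 0.179), and Fcgr3, Crisp3 and Tsc22d1 lost it without EBF 1, EBF 2, control 1 or control 2 (0.136, 0.147 and 0.143). Ctla2a lost it without EBF 1, control 1 or control 2 (0.0644), and Gsn without EBF 2, control 1 or control 2 (0.0635); the rest kept it without any 1 array.

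**Figure D1:**
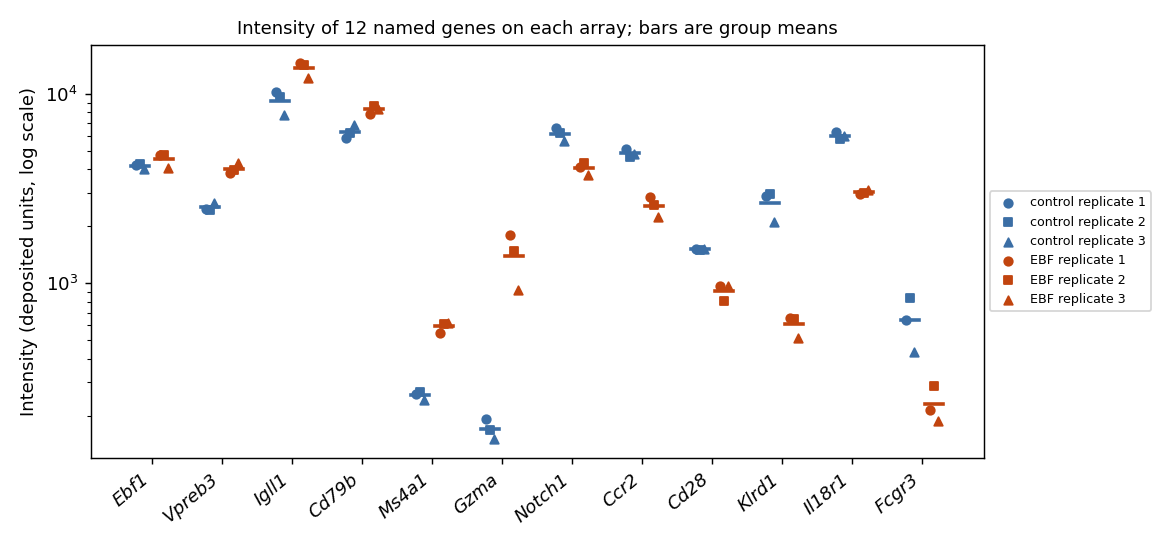
Intensity of 12 named genes on each of the 6 arrays, in deposited units on a log axis; points are arrays, marker shapes are replicate numbers and bars are group means (n = 3). The groups did not overlap for Gzma, Klrd1, Il18r1, Ccr2 and Cd28, whereas the Ebf1 means of 4537 and 4169 lay close together.

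In all, 198 of 18193 genes changed, of which 76 were higher and 122 lower in the EBF arrays, and 28 changed at least 2-fold (17 higher, 11 lower). With the replicate number as a block the fit called 1330 genes (873 higher, 457 lower), among them all 198, each in the same direction. Among the 107 changed genes with several probe sets, 49 had another one changed the same way and 0 the opposite way. Groups did not overlap for 25.2% of all genes, where chance gives 10% on average. Genes vary together, so the share in a single split can lie far from this average. It was not computed for other splits. The count of 198 became 1813 without EBF 3, and 61 without EBF 1, 44 without EBF 2, 44 without control 1, 49 without control 2 and 105 without control 3. Lower genes outnumbered higher ones without control 2 (27 and 22) or control 3 (70 and 35), but not without EBF 1 (30 and 31), EBF 2 (22 and 22), EBF 3 (525 and 1288) or control 1 (21 and 23). The 28 became 51 without EBF 3 and 18 without control 1. Without EBF 3 and control 2 together, the arrays that stood apart from their groups, 814 genes changed.

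Among pre-BCR and BCR genes, the increases were few. Of 23 measured members 2 rose and 0 fell (5 and 2 adjusted over the list alone; 4 and 2 with the block). Vpreb3, a chaperone-like partner of the pre-BCR, rose from 2524 ± 120 to 4038 ± 252 (SD, n = 3 per group; log2 0.67 ± 0.08, adjusted p = 0.0093), and Ms4a1 was the other. The blocked fit added Igll1, the lambda5 surrogate light chain (log2 0.57 ± 0.12; adjusted p = 0.0788, blocked 0.00409), and Cd79b, a signalling chain of the receptor (0.40 ± 0.08; 0.0808, blocked 0.0191). Its partner Cd79a (-0.27), the surrogate light chain gene Vpreb1 (0.08) and the kinase gene Blk (-0.16) passed in neither fit. The list did not shift against other genes by camera (adjusted p = 0.671). Fry's directional test gave an adjusted p of 0.00942, and 0.0572 with the block; one-sided Fisher's exact test gave 0.0813, and 0.0164 with the block. Vpreb3 missed the threshold without EBF 2, control 1 or control 2 (highest adjusted p 0.0635), while Igll1 and Cd79b passed it without EBF 3 (0.0200 and 0.0410), where 4 members rose and 2 fell. Without EBF 2, control 1 or control 2, 1 member rose.

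Of 26 B lineage transcription factors 0 changed by limma, also adjusted over the list alone, and 7 had an unadjusted p below 0.05. With the block, Foxo1 (log2 0.35 ± 0.17; adjusted p = 0.301, blocked 0.0401) and Bach2 (0.31) were higher and Irf8 (-0.50 ± 0.12; 0.0989, blocked 0.0148), Gfi1b (-0.49) and Runx1 (-0.34) lower. Without EBF 3, 2 members were lower, Irf8 (0.0343) among them. Values for Ikzf3 (0.27), the coactivator gene Pou2af1 (0.14) and Id3 (-0.21) passed in neither fit. The median and mean of this list were both 0.01 and camera's direction, relative to other genes, was down (adjusted p = 0.747). In the V(D)J recombination list, Dntt, the terminal transferase that adds N nucleotides, fell from 2549 ± 340.5 to 1547 ± 54.2 (SD, n = 3 per group; log2 -0.70 ± 0.10, adjusted p = 0.0226). It was the 1 of 14 members to change (1 lower and 6 higher adjusted over the list alone), and camera gave an adjusted p of 0.286. The blocked fit added Lig4, a DNA ligase of end joining (log2 0.57; blocked adjusted p = 0.00943), and Rag1, a subunit of the recombinase, had a log2 difference of 0.30 ± 0.10 (adjusted p = 0.191). Dntt missed the threshold without EBF 1, EBF 2, control 1 or control 3 (highest adjusted p 0.106), and 2 members rose without EBF 3.

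Of 22 genes described as repressed by Pax5, 7 fell, 1 rose and 14 did not pass (8 fell and 1 rose adjusted over the list alone; 8 and 2 with the block). Beside Klrd1, the chemokine receptor gene Ccr2 fell from 4859 ± 237 to 2557 ± 316 (SD, n = 3 per group; log2 -0.92 ± 0.10, adjusted p = 0.00675) and the T cell costimulatory receptor gene Cd28 fell by 0.71 (adjusted p = 0.0118). Notch1, a receptor that drives T cell fate, fell by 0.59 ± 0.09 (adjusted p = 0.0286), and Ramp1, the integrin gene Itgal and Emb fell by 0.73, 0.48 and 0.39. Ccl9, a chemokine gene, rose by 0.90 (adjusted p = 0.00906), whereas Csf1r (-0.01) and Flt3 (-0.12), receptors of myeloid and early progenitor cells, passed in neither fit. The excess of changed genes, 8 of 22 against 1.09% of all genes, had an adjusted p of 9.11e-10 by one-sided Fisher's exact test, which takes genes as independent. Other fixed lists held 13 of the 22 and 5 of the 8. Camera gave an adjusted p of 6.31e-07 and, with an estimated correlation, an adjusted p of 0.0814. Fry's adjusted p was 0.00867, and 0.0572 with the block. The number that fell was 3 without EBF 1, 3 without EBF 2, 2 without control 1, 2 without control 2 and 4 without control 3, and it was 7 without EBF 3, where 2 rose, and 7 without EBF 3 and control 2. Among these genes Klrd1 and Ccr2 kept the call without any 1 array, Cd28 lost it without control 1 or control 2 (highest adjusted p 0.0711), Ccl9 without EBF 2 or control 1 (0.0565) and Notch1 without EBF 1, EBF 2, control 1 or control 2 (0.138).

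Of 39 myeloid genes 6 fell and 0 rose (7 and 0 adjusted over the list alone; 9 and 0 with the block). Fcgr3 and Ccr2 were joined by the lysozyme genes Lyz1 (log2 -0.75 ± 0.08) and Lyz2 (-0.48 ± 0.07) and by Tyrobp (-0.71 ± 0.11) and Fcer1g (-0.58 ± 0.07), signalling adaptors shared by myeloid and NK cells. The myeloid regulators Cebpa (-0.08) and Spi1 (-0.21) passed in neither fit. One-sided Fisher's exact test gave an adjusted p of 3.54e-05. Camera gave 0.00207, and an adjusted p of 0.313 with an estimated correlation. In the NK and innate lymphoid list of 20, Gzma rose and Klrd1, Il18r1 and Il18rap fell (2 rose and 4 fell adjusted over the list alone; 1 and 4 with the block), with an adjusted p of 3.64e-04 by one-sided Fisher's exact test and 0.286 by camera. The median of this list was 0.02, its mean was -0.03 and camera's direction was down. Ccl5 (log2 -0.07), Prf1 (0.02) and Gzmb (0.01) were among the members that passed in neither fit. Id2, which antagonises E proteins and is needed for NK cells, had -0.05 at its brightest probe set and fell from 645 to 304 at another (adjusted p = 0.0104). The number of myeloid genes that fell was 2 without EBF 1, EBF 2, control 1 or control 2 and 4 without control 3, and 2 rose without EBF 3. Without EBF 1, EBF 2 or any control, 2 NK genes fell.

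Of 23 T cell genes 2 fell, Cd28 and Cd5 (log2 -0.67 ± 0.08, adjusted p = 0.0121), and 3 did so adjusted over the list alone. The blocked fit called 4, adding Ly6d and Thy1, and Gata3 (-0.05) passed in neither fit. Camera gave an adjusted p of 0.00124, and an adjusted p of 0.294 with an estimated correlation. In the adhesion and homing list of 25, Ccr2, Itgal and Ccr9, a thymus and gut homing receptor gene (-0.73 ± 0.13, adjusted p = 0.0456), fell and 0 genes rose (7 and 0 adjusted over the list alone). With the block 8 fell, among them the integrin genes Itga4 and Itgb7 and the selectin ligand gene Selplg. One-sided Fisher's exact test gave an adjusted p of 0.0116, camera 2.32e-07, and camera with an estimated correlation an adjusted p of 0.0814. Fry's adjusted p was 0.00867, and 0.0572 with the block. In the stem and progenitor list of 28, Kit, the stem cell factor receptor, fell by 0.79 ± 0.11 at its brightest probe set (adjusted p = 0.0187). Its other probe set had -0.16 (adjusted p = 0.273, blocked 0.242). Adjusted over the list alone, 2 members rose and 3 fell. The blocked fit called 3 higher and 4 lower there. Camera gave 0.0863, and one-sided Fisher's exact test an adjusted p of 0.380, and 0.0126 with the block. Notch1 was the 1 of 24 Notch pathway genes to change, also adjusted over the list alone (camera adjusted p = 0.475). Cd5 lost the call without EBF 1, EBF 2 or control 1 (highest adjusted p 0.0819), and Kit and Ccr9 without EBF 1, EBF 2, control 1 or control 2 (0.0995 and 0.200). The adhesion genes that fell numbered 6 without EBF 3, 1 without EBF 1, EBF 2, control 1 or control 2, and 2 without control 3. Without EBF 3, 2 T cell genes rose, 3 stem and progenitor genes rose and 4 fell, and 1 Notch pathway gene rose.

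Of 37 cell cycle genes 0 changed by limma, with 13 higher and 0 lower at an unadjusted p below 0.05 (3 higher adjusted over the list alone), and their median log2 difference was 0.16. The blocked fit called 4 higher: E2f2, a regulator of S phase entry (log2 0.45 ± 0.09; adjusted p = 0.0625, blocked 0.0187), Rrm2, a ribonucleotide reductase subunit (0.37 ± 0.09; 0.109, blocked 0.0235), Mki67 and Plk1. Camera gave an adjusted p of 5.80e-06, and an adjusted p of 0.313 with an estimated correlation. Of the 11 lists that camera called with the preset correlation, this was the 1 called higher. Without EBF 3 and control 2, camera called 4 lists, 0 of them higher, so the call of this list as higher was lost. In the IL-7 receptor list of 22, Myc, a driver of growth, rose by 0.51 ± 0.08 (adjusted p = 0.0325; 3 rose and 2 fell adjusted over the list alone). The blocked fit added Il7r (0.42 ± 0.16; 0.221, blocked 0.0224) and Ccnd3 as higher and Bcl2 and Stat3 as lower. Its median was -0.03, its mean 0.01 and camera's direction down (adjusted p = 0.530). One-sided Fisher's exact test gave an adjusted p of 0.380, and 0.0455 with the block. Myc lost the call without any 1 array other than EBF 3 (highest adjusted p 0.159), and E2f2 passed without EBF 3 (0.0210), where 2 genes of the IL-7 receptor list rose and 1 fell.

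Interferon response genes had a median of -0.22, but the arrays overlapped. Against the control mean, the list median was -0.272, -0.272 and -0.057 in EBF 1 to 3. It was -0.058, -0.102 and 0.122 in control 1 to 3. Of 30, Isg20, an antiviral exonuclease, fell by 0.63 ± 0.08 (adjusted p = 0.0145; 2 lower adjusted over the list alone), and the blocked fit called 9 lower and 2 higher, with Irf7, Oasl2 and Usp18 among the lower. One-sided Fisher's exact test gave an adjusted p of 0.380, and 4.33e-05 with the block. Camera gave an adjusted p of 3.93e-04, and an adjusted p of 0.313 with an estimated correlation. Of 19 antigen presentation genes, H2-DMa, a peptide editor of MHC class II, fell by 0.43 ± 0.07 (adjusted p = 0.0418; the same count adjusted over the list alone), and the blocked fit added Cd74 as higher and H2-Ob as lower. Camera gave 0.0168 and, with an estimated correlation, an adjusted p of 0.213. Fry's adjusted p was 0.0368, and 0.0942 with the block. Of 22 p53 targets and apoptosis genes, Pmaip1, the pro-apoptotic Noxa gene, fell by 0.94 ± 0.14 (adjusted p = 0.0274; 2 lower and 1 higher adjusted over the list alone), and the blocked fit added Perp as higher. Camera gave 0.00995 and, with an estimated correlation, an adjusted p of 0.213. Of 8 Id protein genes, read at their brightest probe sets, 0 changed by limma, in either adjustment. Of these 0 had an unadjusted p below 0.05, with Id4 at -0.20 ± 0.10 and Lyl1 at -0.16 ± 0.08. Camera gave 0.0436 and, with an estimated correlation, an adjusted p of 0.313. At another probe set Id2 fell from 645 to 304 (limma adjusted p = 0.0104), while its remaining probe set did not pass. Isg20 lost the call without EBF 1, EBF 2, control 1 or control 2 (highest adjusted p 0.0927), Pmaip1 without EBF 1, EBF 2 or control 1 (0.109) and H2-DMa without any 1 array other than EBF 3 (0.192). Without EBF 3, 7 interferon genes fell and 3 rose, and 2 antigen presentation and 2 p53 genes fell and as many rose. The camera calls were lost without EBF 3 for p53 (0.0508), without EBF 3 or control 3 for antigen presentation (0.0851 and 0.0579) and without EBF 3, control 2 or control 3 for Id proteins (0.137, 0.209 and 0.0624).

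Lists for other cells and for sample handling also moved between arrays. Of 33 ST2 stromal genes, Igfbp4, an IGF binding protein, fell from 11673 ± 307 to 6574 ± 253 (SD, n = 3 per group; log2 -0.83 ± 0.07, adjusted p = 0.00222), also with any 1 array left out, and it was the 1 call adjusted over the list alone. The stromal genes had a median of -0.18; camera gave 0.00735, and an adjusted p of 0.569 with an estimated correlation. Stromal transcripts such as Col1a2 were found on all arrays (3507 ± 915 in the EBF and 4813 ± 1374 in the control arrays, SD, n = 3 each). Of 30 stress and immediate early genes, Trib3 rose by 0.59 ± 0.10 (adjusted p = 0.0453; 1 higher and 2 lower adjusted over the list alone), and it lost the call without any 1 array other than EBF 3 (highest adjusted p 0.200). The blocked fit called 1 higher and 3 lower, with Fos and Ier3 among the lower. Their median deviation was 0.35 in control 2, 0.07 in EBF 2 and -0.17 to -0.26 in the other 4 arrays, and camera gave 0.0436, with an adjusted p of 0.704 for an estimated correlation. Of 18 ribosomal protein genes 0 changed by limma, in either adjustment, and 0 had an unadjusted p below 0.05, with Rps6 at 0.12 ± 0.08 and Rpl4 at 0.08 ± 0.07 (camera adjusted p = 0.817). The stromal camera call was lost without EBF 3 (0.121) and the stress call without EBF 3 or control 2 (0.474 and 0.755). Members shared with another fixed list numbered 2 of the B lineage transcription factors, 5 myeloid, 3 T cell, 2 NK, 5 stem and progenitor, 3 Notch, 5 Id, 1 IL-7 receptor, 2 adhesion, 1 p53 and 1 stress gene.

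**Figure D2:**
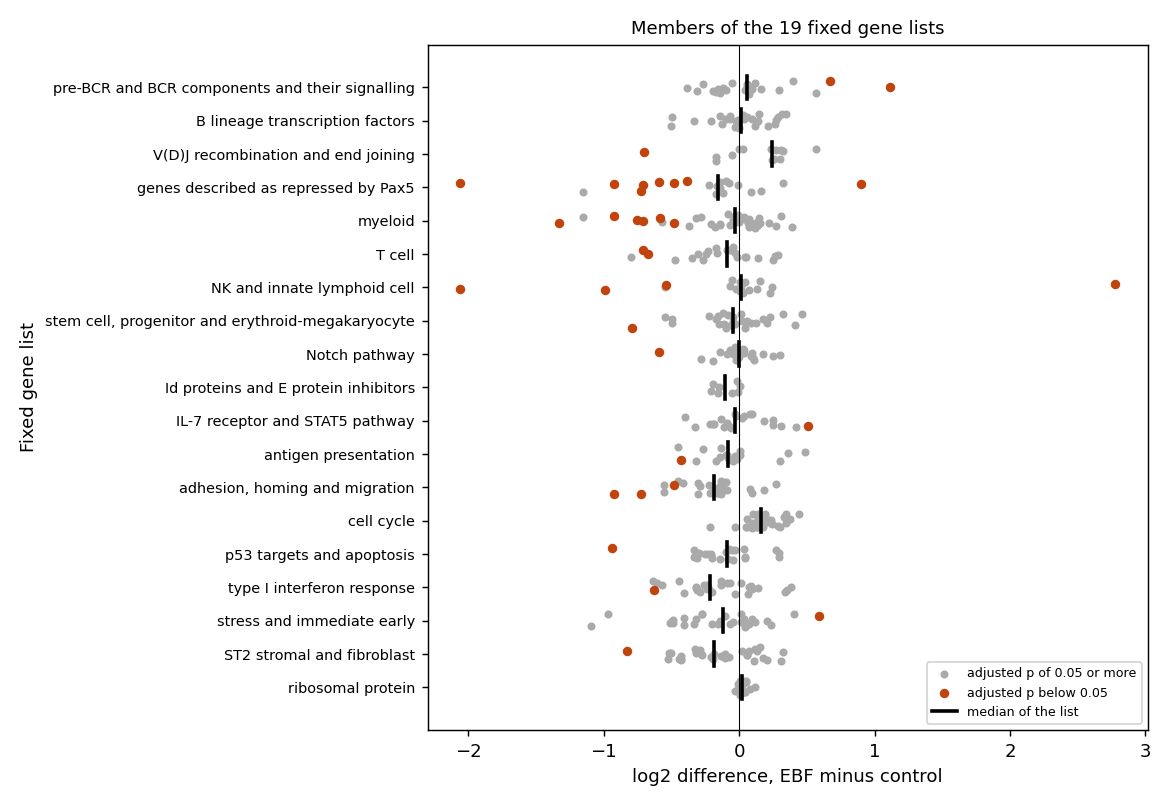
Log2 differences (EBF minus control) of the measured members of the 19 fixed lists; points are genes at their brightest probe set, coloured points have an adjusted p below 0.05 and black bars are list medians. Most coloured points of the Pax5-repressed and myeloid lists lie below 0, with 7 and 6 genes lower.

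The arrays did not group by virus alone. The first principal component, over probe sets of above-median brightness, held 51.2% of the variance and placed EBF 1 and EBF 2 at -24.5 and -19.9, EBF 3 at 0.55 and the controls at 8.50 to 18.7. EBF 3 correlated with control 3 at 0.987 and with EBF 1 and EBF 2 at 0.977 and 0.981, a correlation across probe sets, which are not independent replicates. Control 2 read 15082 at the 3' probe set of 18S ribosomal RNA, against 4385 to 6798 on the other 5 arrays. The 5' probe set of 18S was lower in every EBF array (6702, 8081 and 10503) than in every control (10733, 16531 and 11024), and the 3 probe sets for 18S had log2 differences of -0.59, -0.59 and -0.73 (limma adjusted p over the control probe sets 0.568, 0.400 and 0.400).

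**Figure D3:**
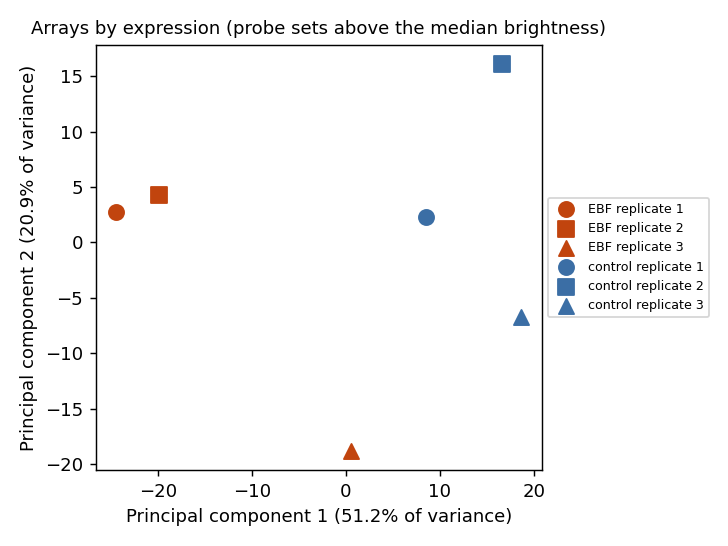
The 6 arrays on principal components 1 and 2 of log2 intensity, with the percent of variance on each axis; colours are groups and marker shapes are replicate numbers. EBF 3, at 0.55 on component 1, lies between EBF 1 and EBF 2 and the controls.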

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

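No named gene that passed changed direction under any alternative, but calls and counts depended on the fit and on single arrays. Quantile normalization, median centring and the filter on dim probe sets left the 394 probe sets, 198 genes, 28 genes changed at least 2-fold and 11 lists called by camera with the preset correlation (0 of 19 with an estimated correlation, lowest adjusted p = 0.0814) within 1.5 times, at 382, 191, 29 and 10, 408, 203, 31 and 9, and 444, 248, 21 and 10. Fry's directional test passed for the pre-BCR, Pax5-repressed, adhesion and antigen presentation lists alone, and with the block for no list (lowest adjusted p = 0.0572). Among the lists called by camera, fry missed cell cycle (adjusted p = 0.0645), T cell (0.105), myeloid (0.118), p53 (0.132) and interferon genes (0.183). It also missed the Id (0.272), stromal (0.388) and stress genes (0.778). Among the lists, the camera call of the stress genes was lost with quantile normalization (adjusted p = 0.119), centring (0.0725), the filter (0.130) and the higher pseudocount (0.0538), and that of the Id genes with centring (0.0536) and the filter (0.233). The NK list gained a call with the filter (0.0367) and the stem and progenitor list with the mean of a gene's probe sets (0.0239); the cause was not tested. Centring lowered the share of higher probe sets from 39.3% to 29.2%, and of the genes changed at least 2-fold it called 15 higher and 16 lower, against 17 and 11. With a trended and robust variance the fit called 611 probe sets and 318 genes, with array weights 3907 and 1655, and with the replicate block 3280 and 1330. Array weights called 1156 genes higher and 499 lower, and the trended and robust variance 144 higher and 174 lower. The cause was not tested. With the block 65.6% of the changed genes were higher, against 38.4% without it. None of the 198 changed direction, and the genes that the block added were mostly higher. Why they were so was not tested. The block also raised the lists called by one-sided Fisher's exact test from 4 to 8. Apart from these and the calls and counts printed beside their genes and lists, the block changed no other call of a reported gene or list. With the replicate number as a random block, chosen after seeing the data, 1286 probe sets and 591 genes (314 higher, 277 lower) passed. The cause was not tested. The mean of a gene's probe sets gave 337 genes (170 higher, 167 lower), and the cause was not tested. The stricter threshold of 0.01 gave 48 (25 higher, 23 lower). The lower pseudocount gave 279 probe sets and 144 genes, and the higher one left 18 genes at 2-fold, since it shrinks the differences of dim genes. Across single arrays and replicate numbers left out, the counts ranged from 4 to 4287 probe sets, from 1 to 1813 genes, from 1 to 53 genes at 2-fold and from 6 to 11 lists. The highest counts of probe sets and genes came without EBF 3 or number 3 and the lowest without number 2, while for lists the lowest came without EBF 3. Without EBF 3 more probe sets and genes passed although fewer arrays were left; the cause was not tested. Without EBF 3 and control 2, chosen after seeing the data, 1887 probe sets, 814 genes, 51 genes at 2-fold and 4 lists passed, and the median of the stress genes turned from -0.12 to 0.11; the cause was not tested. With the stromal median as a covariate, also chosen after seeing the data, 97 probe sets and 49 genes passed, a fit with fewer degrees of freedom. One-sided Fisher's exact test called 4 lists, the Pax5-repressed, myeloid, NK and adhesion lists, against all genes and again 4 against genes of above-median brightness, a count of changed members, where camera weighs all members. Of the 65 named genes measured, 64 kept their status, called or not called, with quantile normalization, 63 with centring and 58 with the lower pseudocount. It was kept by 45 with the stromal covariate, 44 without control 1, 29 without number 1 and 27 without number 2, where fewer arrays were left. In these settings the other genes lost a call. With the block 58 kept their status and 7 gained a call. Of the 39 that passed, 21 lost the call without at least 1 array and 18 kept it without any 1.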

Other observations

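Of the tests below, the 2 on EBF 3 and the one on NK cells were chosen after the result was seen. The stromal covariate used below was also added after seeing the data. The genes of this and the next paragraph were likewise chosen after their values were seen. Ret, the receptor kinase that signals with GDNF-family co-receptors, rose at 1 probe set from 112 ± 19.3 to 321.4 ± 19.7 (SD, n = 3 per group; log2 1.31 ± 0.11, limma adjusted p = 0.00215), levels below the highest Bacillus control of 410. Its brightest probe set had 0.44 ± 0.09 (adjusted p = 0.0775, blocked 0.0115). Of the 5 probe sets of Gfra2, which encodes such a co-receptor, 3 rose (log2 1.75, 1.50 and 1.13), while the other values were 0.52 (adjusted p = 0.159, blocked 0.0104) and 0.13.

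Genes with several probe sets did not always move as their brightest one. Hipk2, a nuclear kinase, rose at 4 of 8 probe sets, the largest of them by 1.40 ± 0.15 (SE, n = 3 per group; limma adjusted p = 0.00693), but its brightest had 0.33 ± 0.12 (adjusted p = 0.195), so it is absent from the 198 changed genes. A further Hipk2 probe set passed only with the block (log2 0.41; adjusted p = 0.202, blocked 0.0197). Cndp2, a dipeptidase, rose at both of its probe sets, by 1.09 ± 0.11 and 1.40 ± 0.15 (adjusted p = 0.00511 and 0.00603). Ccr2 fell at 2 other probe sets (log2 -2.16 and -1.91), by more than at its brightest (-0.92), and its remaining probe set had -0.23 (adjusted p = 0.176). Tubb3, a neuronal tubulin, and Arntl, a circadian clock factor, had 1.39 ± 0.34 and 1.12 ± 0.24 and passed only with the block (adjusted p = 0.112 and 0.0821, blocked 1.32e-04 and 4.25e-04).

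EBF 3 lay nearer to the controls than EBF 1 and EBF 2 did; if cells without the EBF virus had diluted this array, all genes should have lost the same part of their response on the intensity scale. Among the 500 genes ranked first by p without EBF 3, not the set of 198, the 44 changed at least 2-fold kept 0.72 of it and the other 456 kept 0.30, a difference of 0.418 (95% bootstrap interval 0.265 to 0.536). The interval came from resampling genes within this array, so it does not measure the spread between arrays. The genes were ranked by the arrays that also set the full response, so smaller changes may be overstated there. Treated the same way, EBF 1 and EBF 2 gave differences of -0.02 and 0.04. As far as a single array can tell, the values speak against dilution as the only cause. Higher genes kept 0.21 and lower ones 0.79, a split with no interval. A shift shared by the arrays numbered 3 stays open: the correlation of 0.505 between the deviations of EBF 3 and control 3, against 0.316 and 0.251 for the other numbers, is the value that the pairing was read from, so it is no separate test. The labels give no day or batch, and a lower dose of EBF in this culture was not tested.

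NK receptor genes were lower in the EBF arrays, and fewer NK cells among the sorted cells might account for this. Against this, the granule gene Gzma differed by 2.78 in the other direction, and the chemokine gene Ccl5 read 1344 in the EBF and 1407 in the control arrays. With it go Nkg7, another granule gene (log2 -1.70), Fcgr3 (-1.33), Tyrobp (-0.71), Fcer1g (-0.58) and Il18rap (-0.54). Since the genes part in this way and Gzma may be made by other cells, a loss of NK cells stays open. A change within the sorted cells, as an effect of the virus they were given, stays open too and was not tested.

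Less RNA from ST2 stromal cells in the EBF arrays could lower Igfbp4: the cells were sorted for GFP, per the labels, yet 28 of 33 stromal genes read above the highest Bacillus control in both groups, and whether ST2 cells are their source was not tested. With the median of the other stromal genes as a covariate, Igfbp4 still differed by -0.82 ± 0.08 (SE, n = 3 per group; limma adjusted p = 0.0190). Over the 198 changed genes the median size of the difference with the covariate was 1.02 times that without it, and 198 kept their sign, but 49 still passed in this fit, which has fewer degrees of freedom. The median of the other stromal genes overlapped between the groups (0.12, -0.18 and -0.11 in EBF 1 to 3, -0.14, 0.15 and 0.08 in control 1 to 3). Igfbp4 itself read 6324 to 6831 in the EBF and 11406 to 12009 in the control arrays, so it did not follow that median. This speaks against a stromal RNA amount shared by these genes as the only cause of the difference in Igfbp4. The covariate fit adds little to this, since Igfbp4 was itself picked as a changed gene. For the other changed genes, as a set or one by one, the covariate values cannot decide. Genes picked for a small spread within groups could hardly follow a covariate that varied within groups. No other biological explanation was tested.

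The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of them, the real one, reached counts as large as those reported: 394 probe sets, 198 genes and 28 genes at 2-fold, against at most 0 in any other split. For lists called by camera with the preset correlation, of which 0 passed with an estimated one, it was again 1, with 11 against at most 10 in another split. Of these splits 4 part all 3 pairs of same-numbered arrays; with the block the real one gave 1330 genes and 11 lists, and the others at most 0 genes and 10 lists. The splits are too few for a share under 0.05.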
